A study of Mus musculus with 2 samples.

How the data were processed

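The series holds 2 ATAC-seq libraries of FACS-sorted tdTomato Wnt4-lineage cells from mouse kidneys at E18.5, late in gestation, 1 from control and 1 from Brg1 cKO kidneys, made from 50000 cells per reaction per the labels' protocols. The labels enter the library source as transcriptomic and the molecule as total RNA, although the protocol they describe is ATAC-seq on nuclei, and the values were read as ATAC-seq peaks. The cell type label names the Wnt4 lineage for the cKO library and reads only control for the other, so that both libraries hold sorted Wnt4-lineage cells rests on their titles, the shared protocol and the series' design text; every difference between them assumes it. Per the submitters' processing notes, reads were handled with Trim Galore, SAMtools and Genrich on mm10. The aligner, the Genrich settings, tool versions, the treatment of duplicates and mitochondrial reads, and whether read ends were shifted for the transposase are not given in the sources used here.

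The deposited files are 1 peak list per library in narrowPeak form. The authors' score per peak is a whole number capped at 1000, reached by 44.2% of control and 39.6% of cKO peaks, and was not used for ranking. The deposited signal per peak is the area under the peak caller's curve, at least 200 in both lists, and is not scaled between libraries. The deposited -log10 p and -log10 q are the authors' peak caller's values; the lowest -log10 q was 1.42 in the control and 1.35 in the cKO list, so less significant peaks are not part of the lists. These values depend on the depth and background of a library, so they were used only to rank peaks within a list, and no score, area or p was compared between lists. The lists give no read counts, so the depth per library is unknown, and a library sequenced less deeply or with more background yields fewer weak peaks. No 2 peaks of a list lay closer than 101 bp.

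Coordinates were taken as mm10 and are given 1-based. Genes came from the RefSeq table of GRCm38.p6, the assembly of mm10, which held 49976 genes on chromosomes, 21896 of them protein-coding. No peak ran past an mm10 chromosome end, and 27.5% of control and 31.9% of cKO peaks lay within 1000 bp of a gene end, against 11.8% and 12.3% after all peaks were moved by 1 Mb. The table gives no strand, so the transcription start sites foreseen in the design were replaced by both annotated ends of a gene, and peaks described as near a gene end include those at 3' ends. No genome sequence was used here, so the planned comparison of transcription factor motifs was not run. All genes of the 20 lists were found in the table.

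A peak counted as found in the other library when it overlapped a peak there by at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Peaks were divided into 10 classes of strength by the caller's p within their own list, shown also as 5. Near and distal peaks were compared within these classes, weighted by all peaks of a class, with an interval by the normal approximation from binomial counting error, and by the Mantel-Haenszel odds ratio. Each peak was assigned to the protein-coding gene with the end nearest to its summit, within 100000 bp, which held for 87.5% of the peaks of each list; the design left open whether other genes could be assigned, and this choice was made before any list was examined. For each list, the share found was compared with the share among all peaks of the same strength class and position, and the mean difference was placed among 10000 random lists of protein-coding genes matched on number of peaks. A place in the lowest or highest 2.5% was taken to stand apart; it describes these 2 libraries and is no p-value, since there is 1 library per genotype.

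The tests, the 20 gene lists, the rule for named genes and the first group of other settings given below were fixed before the data were examined. The lists held 314 genes, 5 of them in more than one list. The rule took Smarca4, Smarca2 and Wnt4 always. From each list it took at most 4 genes, the 2 with the highest and the 2 with the lowest number of control-only minus cKO-only peaks, leaving out genes at 0. It also took the 10 genes with the lowest share found among those with at least 10 peaks, in each direction, and the nearest genes of the 5 most significant unmatched peaks of each library. Genes that differ at a gene end, and others marked as chosen after their values were seen, are exceptions. Some genes that the rule or the lists name are not reported here. A further 4 lists of podocyte, progenitor, interstitial and proximal tubule genes sharing no gene with the first lists were written after the first results and before their own were seen.

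The method was tested on simulated data. Of 100 lists of 20 genes whose peaks were lowered by 12 points, 97% fell below percentile 2.5. Of 100 unchanged lists, 8% fell outside the middle 95%, where 5% is nominal, so the percentiles may be too extreme. All these lists were matched to the podocyte list in peaks per gene, and their peaks were drawn independently. Smaller lists and neighbouring peaks lost together were therefore not covered. A difference of 5 points between near and distal peaks was recovered as 5.01 points with an SD of 0.395 over 20 simulated data sets. Before that difference, all peaks of a strength class had the same simulated share. Whether near peaks are stronger than distal ones within a class was therefore not covered.

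The first group of other settings was an overlap of 50% of both peaks, the summit inside the other peak, the more significant 50% of each list, lists of equal length, autosomes only, merging of peaks within 100 bp, the strongest of the 5 classes alone, gene-end windows of 500 and 2500 bp, ends of protein-coding genes only, no adjustment for strength, assignment within 50000 bp and assignment to gene bodies with 5000 bp around. Strength by area, by p and area together, this last with equal list lengths, and assignment to any annotated gene were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1.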

Results

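Chromatin accessibility was profiled by ATAC-seq, in which a transposase cuts open DNA, in tdTomato-positive Wnt4-lineage cells sorted from kidneys at E18.5, shortly before birth. Wnt4 is switched on as kidney mesenchyme turns into epithelium, so its lineage includes cells of the nephron. One library, of 77529 peaks covering 84.6 Mb with a median width of 838 bp, came from control kidneys. The other came from kidneys in which Brg1, the ATPase of the BAF chromatin remodelling complex encoded by Smarca4, was deleted (cKO), and held 61210 peaks covering 71.4 Mb with a median width of 900 bp. Each genotype had 1 library, so there was no replicate spread and no test between genotypes was made. Intervals are 95% intervals, exact binomial for shares and by a normal approximation for differences between near and distal peaks; they cover counting error only and describe these 2 libraries rather than the genotypes.

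The first comparison asked how much of the open chromatin of control cells was also called without Brg1. Of the control peaks, 57486 of 77529 overlapped a cKO peak (74.1%, 73.8 to 74.5%), and 20043 did not. In the other direction 57588 of 61210 cKO peaks overlapped a control peak (94.1%, 93.9 to 94.3%), leaving 3622 called in the cKO library alone. The libraries had 64.7 Mb in common, a Jaccard index of 0.710. Peaks without a counterpart were weak: from the weakest to the strongest of 5 equal strength classes, 38.5%, 56.4%, 81.1%, 94.8% and 99.9% of control peaks overlapped a cKO peak, against 78.9%, 92.4%, 99.3%, 99.9% and close to all of the cKO peaks. With the control list reduced to its 61210 most significant peaks the shares were 83.6% and 84.3%; lists of equal length give nearly equal shares whatever the cause, so this sets the level of overlap and does not show where the asymmetry comes from. The depth of sequencing is unknown here, so a peak missing from a list is not shown to be closed chromatin.

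Peaks beside genes and peaks far from them were compared next. Control peaks within 1000 bp of an end of an annotated gene overlapped a cKO peak in 90.2% of 21314 cases, and distal control peaks in 68.1% of 56215. Peaks beside genes were stronger, and within strength classes the difference was 4.73 percentage points (3.98 to 5.48) in place of 22.1. With classes by peak area it was 3.21 points, and by p and area together 3.08. Its size therefore depended on how strength was measured. The cKO peaks gave the same order, 98.1% of 19497 beside genes and 92.2% of 41713 distal ones, with 1.61 points (1.14 to 2.07) within classes by p. The odds ratios across strength classes, 1.48 for the control list and 1.44 for the cKO list, were alike, so the better recovery of peaks beside genes was not particular to one direction.

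**Figure D1:**
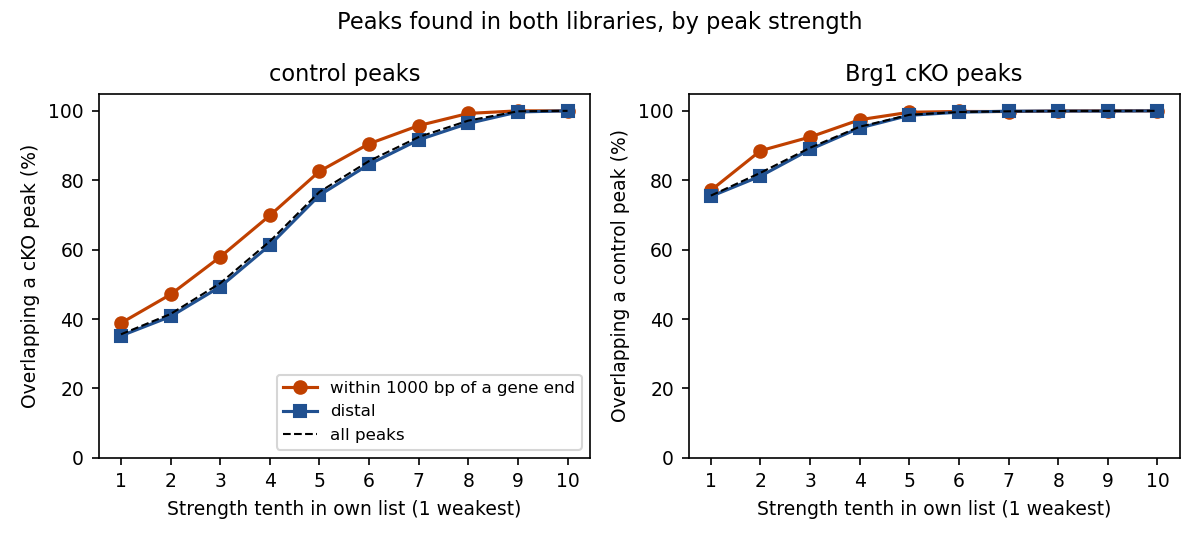
Share of peaks (%, vertical axis) overlapping a peak of the other library, by strength class within the peak's own list (horizontal axis, 1 weakest to 10 strongest), for control peaks on the left and Brg1 cKO peaks on the right. Circles are peaks within 1000 bp of a gene end, squares distal peaks and the dashed line all peaks; the control curve starts lower, and both reach 100% in the strongest class.

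Most genes with an open end in one library had one in the other. Among 21896 protein-coding genes, 14800 had a control peak and 14496 a cKO peak within 1000 bp of either end, and 14432 had both. A peak was called in the control alone at 368 genes and in the cKO alone at 64. Markers in the fixed lists with a control peak alone were Cubn and Slc3a1 of the proximal tubule, Cldn10 of the thick ascending limb, the epithelial sodium channel gene Scnn1b, the matrix gene Lum and the macrophage genes Csf1r, C1qa and Fcgr1. Those with a cKO peak alone were Kcnj1, a potassium channel gene of the ascending limb, and the neural gene Neurod1. These counts concern the 1000 bp window only, and a peak in it may overlap a peak of the other library that ends outside it. All 3 cKO peaks assigned to Kcnj1 overlapped a control peak. With the control list reduced to the length of the cKO list the counts were 203 and 181, a setting that evens them largely by its construction.

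Smarca4, the deleted gene (mm10 chromosome 9, 21616106 to 21704230), had a peak at a gene end in both libraries, and 2 of its 3 assigned control peaks overlapped a cKO peak. Peaks of open chromatin at this gene cannot show whether its deleted part is missing, so they do not check the genotype labels. Smarca2, which encodes the other ATPase of the complex (chromosome 19, 26605073 to 26778321), kept 7 of 8 control peaks, and all 7 of its cKO peaks overlapped a control peak. Wnt4, the gene that marks the lineage (chromosome 4, 137277635 to 137299501), had a gene-end peak in both, kept 14 of 20 control peaks and had 15 of 16 cKO peaks in the control.

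Podocyte genes stood furthest apart. Podocytes are the filtering cells of the glomerulus, and 152 of the 252 control peaks assigned to 20 podocyte genes overlapped a cKO peak (60.3%, 54.0 to 66.4%), where 72.1% was expected from peaks of the same strength and position. The difference of -11.8 points lay at percentile 0.06 of 10000 random gene lists matched on number of peaks, whose middle 95% ran from -7.24 to 5.43. Of the 20 genes, 18 had more unmatched control peaks than unmatched cKO peaks, within the 13 to 19 of the middle 95% of random lists. In the other direction 161 of 167 cKO peaks of these genes overlapped a control peak (96.4%, percentile 81.09), but with overlap of 50% of both peaks required, these cKO peaks stood at -11.5 points (percentile 0.03).

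Podxl, which encodes the sialomucin podocalyxin of the podocyte surface (chromosome 6, 31519493 to 31563937), kept 12 of 29 control peaks and had 14 cKO peaks, all matched. Wt1, a transcription factor needed for podocyte identity (chromosome 2, 105126529 to 105173614), kept 14 of 30 and had 16 cKO peaks, all matched. The least affected genes named by the rule were Tcf21, with 11 of 13 control peaks found, and the collagen IV gene Col4a4, with 5 of 7. Other members, chosen after their values were seen, included the phosphatase gene Ptpro with 4 of 12, Vegfa with 10 of 20, the slit diaphragm genes Kirrel with 10 of 18 and Nphs1 with 4 of 6, and Synpo with 16 of 20. By strength class the list's control peaks were found in 21.0%, 42.2%, 65.3%, 86.2% and 100% of cases, the last being 38 of 38 peaks. Against random lists matched also on gene length, which themselves had a median of -3.61 points, the list lay at percentile 0.57.

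**Figure D2:**
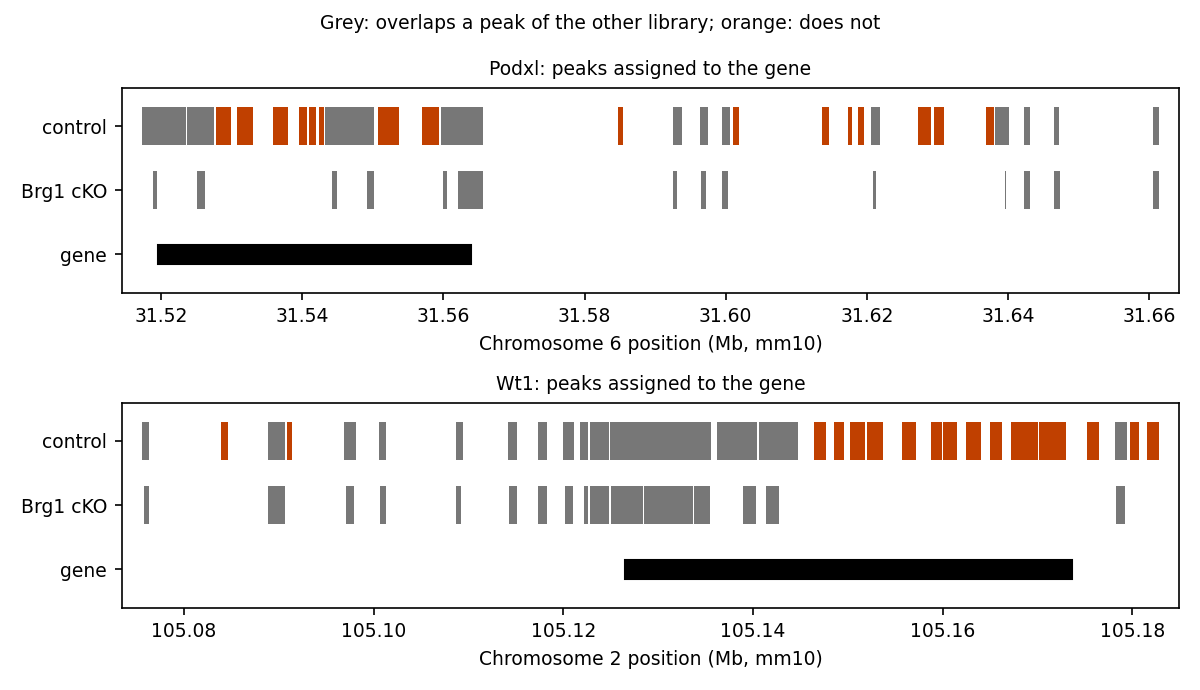
Map of the peaks assigned to Podxl (chromosome 6, above) and Wt1 (chromosome 2, below), with position in Mb of mm10 on the horizontal axis and lanes for control peaks, Brg1 cKO peaks and the gene (black). Grey peaks overlap a peak of the other library and orange peaks do not; 17 of 29 control peaks at Podxl and 16 of 30 at Wt1 are orange, many of them inside the gene, and no cKO peak is.

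Unlike the podocyte list, the tubule lists lay within the range of random lists. For the proximal tubule, which reabsorbs most of the filtrate, 44 of 64 control peaks overlapped a cKO peak (68.8%, 55.9 to 79.8%, percentile 35.48), with 6 of 10 at the endocytic receptor gene Cubn, 4 of 7 at the transcription factor gene Hnf4a, 4 of 6 at Ass1 and 2 of 4 at Fbp1. Loop of Henle genes kept 58 of 70 (82.9%, 72.0 to 90.8%, percentile 96.15), with 11 of 12 at Pou3f3 and all 3 at Ptger3 but 8 of 13 at Sim2 and 0 of 2 at Cldn16. Distal and connecting tubule genes kept 46 of 59 (78.0%, 65.3 to 87.7%, percentile 97.16), with 7 of 8 at the sodium-calcium exchanger gene Slc8a1 and the only peak at Tmem52b, but 3 of 7 at Tfap2b and 4 of 7 at Fxyd2. Genes of the early nephron kept 122 of 164 (74.4%, 67.0 to 80.9%, percentile 65.43), with 8 of 8 at Lhx1, 11 of 16 at Pax8, 3 of 5 at Dkk1 and 13 of 23 at Notch2. These 4 lists lay within the middle 95% of random lists, and each held few enough peaks that differences of several points were not detectable. For the proximal tubule 71.0% was expected, and the interval of its share reached down to 55.9%. A loss as large as the -11.8 points of the podocyte list was therefore not excluded for the proximal tubule by this list. A second proximal tubule list is given below.

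Nephron progenitor and interstitial genes lay above the random lists. Progenitor genes, which mark the self-renewing cap mesenchyme, kept 93 of 111 control peaks (83.8%, 75.6 to 90.1%), 10.4 points above peaks of equal strength (percentile 99.37). All 17 control peaks of Meox1 and 8 of 9 of Six2, genes chosen after their values were seen, were found, as were 10 of 11 at Itga8, 10 of 13 at Sall1 and both at Rspo1, whereas Pax2 kept 17 of 26. Interstitial genes kept 124 of 151 (82.1%, 75.1 to 87.9%), 8.90 points above (percentile 99.14), with 20 of 22 at Meis1 and both peaks of Col3a1 but 17 of 24 at Zeb2 and 5 of 10 at Ntn1. The progenitor list was at percentile 96.25 when strength was taken from peak area, and the interstitial list at 92.53 in the more significant 50% of each list, so both left the extreme 2.5% under some settings.

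Lists for cells outside the nephron and its stroma mostly lay within the range of random lists. That range reached down to -19.2 points for erythroid, -13.4 for immune, -12.3 for housekeeping and -11.9 for smooth muscle and pericyte genes. A loss as large as that of the podocyte list would not have stood apart in these small lists. Neural genes kept 38 of 45 control peaks (84.4%, 70.5 to 93.5%, percentile 98.17), with 5 of 8 at Syt1 and all of those at Neurod1 and Olig2; with the control list at the length of the cKO list the percentile was 83.15. Smooth muscle and pericyte genes kept 42 of 51 (82.4%, percentile 68.22), with 11 of 14 at Cspg4, 6 of 7 at Notch3, 4 of 5 at Des and 2 of 3 at the renin gene Ren1. Collecting duct and urothelium genes kept 78 of 101 (77.2%, percentile 74.74). Within this list unmatched control peaks most exceeded unmatched cKO peaks at Wnt11, with 12 of 17 kept, and at the intercalated cell gene Foxi1, with 3 of 6. Endothelial genes kept 101 of 136 (74.3%, percentile 65.44). The excess of unmatched control over unmatched cKO peaks was largest at the VEGF receptor gene Kdr, with 14 of 21 kept. The tight junction gene Cldn5, with 4 of 9, came next. Immune genes kept 25 of 38 (65.8%, percentile 29.65), with 7 of 11 at Laptm5 and 2 of 4 at Csf1r, and erythroid genes kept 12 of 17 (70.6%, percentile 41.5), with 1 of 4 at the anion exchanger gene Slc4a1. Housekeeping genes kept 43 of 48 (89.6%, percentile 83.73), including 15 of 19 at Ywhaz.

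Pathway lists stayed within the range of random lists. That range reached down to -12.1 points for cell cycle and -12.4 for p53 target genes. A loss as large as that of the podocyte list would not have stood apart in these 2 lists. Genes of the BAF complex kept 88 of 127 control peaks (69.3%, 60.5 to 77.2%, percentile 13.61), and Arid1b, which encodes a DNA-binding subunit, kept 17 of 32, against 12 of 18 at Dpf3 and 6 of 7 at Arid1a. Wnt signalling genes kept 159 of 213 (74.6%, 68.3 to 80.3%, percentile 87.56), with 9 of 19 at the transcription factor gene Lef1, 24 of 33 at Tcf7l2 and all 8 at Tcf7. Notch signalling genes kept 85 of 116 (73.3%, percentile 41.12), with 20 of 26 at Hes1 and 6 of 7 at Nrarp. TGF-beta and matrix genes kept 134 of 174 (77.0%, percentile 86.46). The members with the largest excess of unmatched control peaks were Col4a1, with 19 of 26 kept, and the receptor gene Tgfbr1, with 4 of 10. Cell cycle genes kept 32 of 40 (80%, percentile 34.42), with 7 of 9 at Mki67, and p53 target genes 33 of 40 (82.5%, percentile 61.67), with 8 of 10 at Pmaip1. Over all 20 lists, 4 lay outside the middle 95% of random lists, podocyte below and progenitor, interstitial and neural above. Chance gives 1 nominally and 1.6 at the rate of unchanged lists in simulated data, all of them matched to the podocyte list.

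**Figure D3:**
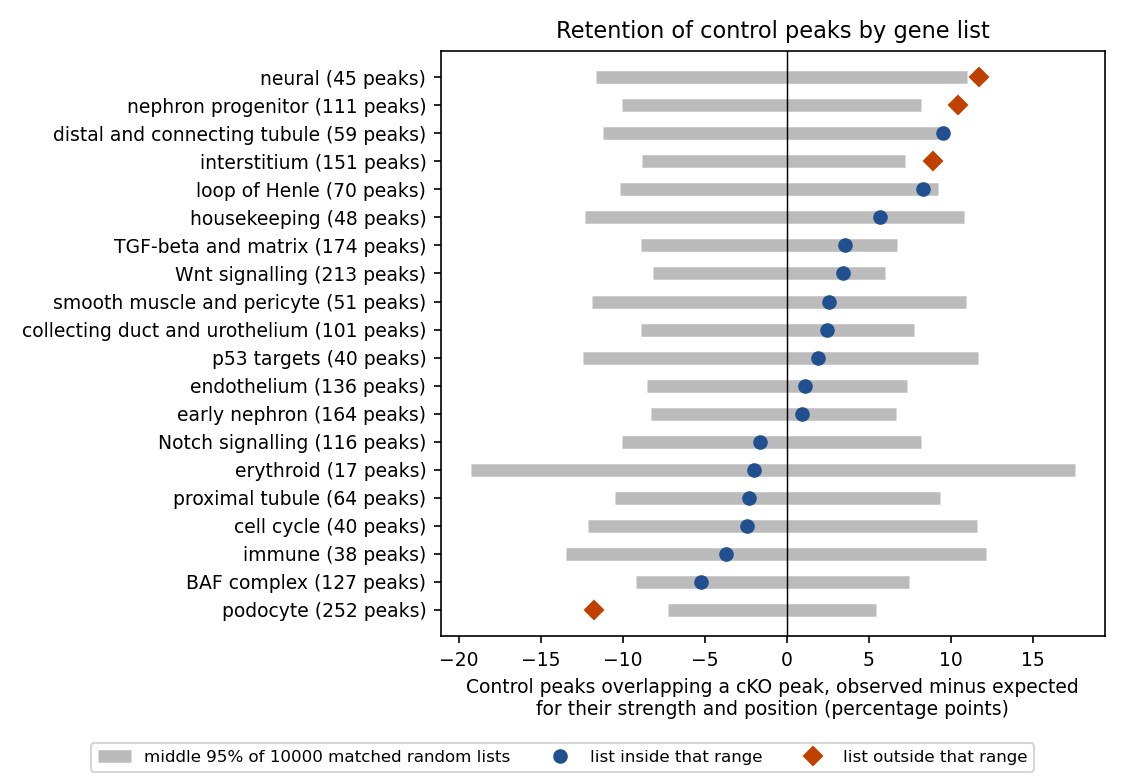
Control peaks of each gene list that overlap a cKO peak, as the observed share minus the share expected from peaks of the same strength and position (percentage points, horizontal axis), with the number of control peaks beside each list. Grey bars are the middle 95% of 10000 random gene lists matched on number of peaks; the podocyte list, at -11.8, lies below its bar and the neural, nephron progenitor and interstitium lists lie above theirs.

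The cKO peaks were examined by list in the same way, to find genes with openings not seen in the control. In the main setting no list lay in the lowest 2.5% of random lists; the lowest was the interstitium list, with 121 of 133 found (91.0%, 84.8 to 95.3%, percentile 4.49), where Col3a1 had 2 of 4 cKO peaks in the control and Meis1 17 of 20. Smooth muscle and pericyte genes had 41 of 45 (percentile 12.34), with 6 of 9 at Notch3. At the other end all 87 cKO peaks of BAF complex genes (percentile 98.03) and 164 of 167 of Wnt signalling genes (percentile 98.93) overlapped a control peak. The remaining lists lay between percentile 30.75, for the 26 peaks of immune genes, and 94.01, for the 45 of proximal tubule genes. With equal list lengths no list lay outside the middle 95%, so the 2 lists above it were not kept. Of the 20 lists, those in the lowest 2.5% under another setting were podocyte with 50% overlap of both peaks (percentile 0.03), nephron progenitor in the more significant 50% of each list (2.07) and interstitium with assignment within 50000 bp (2.43).

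Single genes with many peaks were ranked last. Among 1590 protein-coding genes with at least 10 control peaks, Nell2 kept the smallest share, 1 of 10, followed by 0610040J01Rik with 3 of 13 and Lgr4, a receptor for R-spondins, with 3 of 12. Bod1, LOC115489673, the lipid phosphatase gene Mtmr3, Pacs2, Psapl1, the guidance receptor gene Robo1 and Tnfsf15 each kept 3 of 10. Among 968 genes with at least 10 cKO peaks, Mid1 had the smallest share in the control, 6 of 12, followed by Calcrl, Cpm, the aminopeptidase gene Enpep and the glypican gene Gpc3 with 7 of 10 each, Gm52481 with 18 of 25, and Cdca7, Nln, Sox2 and Wdr11 with 8 of 11 each. Enpep nevertheless had 7 unmatched control peaks against 3 unmatched cKO peaks, Wdr11 4 against 3, and Nln 3 of each. The others had more unmatched cKO than control peaks. Mid1 on chromosome X and Gm52481 on chromosome Y both lie at the edge of the region that the sex chromosomes share. These are the extremes of many small counts, selected as such, and no single gene was tested.

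The most significant control peaks without a cKO counterpart lay 15.3 kb from Grm4 (chromosome 17, 27406469 to 27407761), 11.6 kb from the growth factor gene Pdgfb (chromosome 15, 79983409 to 79985114), 83.2 kb from the oxygen sensor gene Egln3 (chromosome 12, 54286679 to 54287712), inside Ccdc30 (chromosome 4, 119412375 to 119413464) and 35.4 kb from Sipa1l2 (chromosome 8, 125604363 to 125605654). Their -log10 p in the control list ran from 8.38 to 8.96. The most significant cKO peaks without a control counterpart lay inside Mid1 (chromosome X, 169974497 to 169975337), 64.7 kb from the histamine receptor gene Hrh1 (chromosome 6, 114548009 to 114548184) and 86.1 kb from Ddhd1 (chromosome 14, 45744160 to 45744261), and 2 more lay far from any protein-coding gene, 321 kb from Alkbh8 (chromosome 9, 3014298 to 3014519) and 471 kb from Tfec (chromosome 6, 16359721 to 16360326). Their -log10 p in the cKO list ran from 6.43 to 8.28, the highest being the 222 bp peak nearest to Alkbh8. No regions prone to mapping artefacts were filtered out here, so single peaks of this kind may be artefacts. In both lists the strongest of 10 equal classes of peaks, 7752 in the control and 6121 in the cKO, overlapped the other library without exception.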

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

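Settings with strength by area, by p and area together, this with equal lengths, and with any annotated gene were chosen after the data were seen; the others were planned. The podocyte list stayed below percentile 2.5 in all 14 settings run on lists, the main one included, between -18.1 and -9.99 points, as did the second podocyte list, between -22.1 and -8.89. The progenitor and interstitial lists stayed in the highest 2.5% in 11 of the 14 (5.96 to 18.2 and 5.17 to 13.3 points) and the neural list in 7 (5.27 to 19.0 points). With 50% of both peaks overlapping, 69.8% of control and 88.4% of cKO peaks were found, the near minus distal difference was 3.51 points, and the cKO peaks of the podocyte list went from 3.32 to -11.5 points (percentile 0.03). In the more significant 50% of each list, 75.4% and 95.2% were found, Wnt signalling cKO peaks stood at 0.738 points, and among cKO peaks 1 list was outside, the progenitor list, in place of BAF complex and Wnt signalling. With the control list at the cKO length, 83.6% and 84.3% were found, gene-end peaks were private to the control at 203 genes and to the cKO at 181, 0 lists were outside among cKO peaks, BAF complex cKO peaks stood at 0.982 points, and 5 lists were outside among control peaks against 4 in the main setting, without neural and with loop of Henle and TGF-beta and matrix; with strength by p and area as well, these were 0 lists, 0.813 points and 2 lists, podocyte and interstitium. The strongest of the 5 classes was found in 99.9% of control and 99.99% of cKO peaks. Without adjustment for strength the near minus distal difference was 22.1 points, and BAF complex cKO peaks stood at 5.92; with the summit rule they stood at 5.32, the 1 list outside. With ends of protein-coding genes only the difference was 6.08 points, with strength by area 3.21 and by p and area together 3.08; with either of these 2, 0 lists were outside among cKO peaks. Neither BAF complex nor Wnt signalling cKO peaks stayed outside with assignment within 50000 bp, where 1 other list, interstitium, was, or with gene bodies, where 1 other, collecting duct, was and 2 lists were outside among control peaks. Assignment to any annotated gene gave 0 among cKO peaks and put the progenitor list at 18.2 points. Equal lengths even the shares and gene counts by construction; for the rest the cause was not tested. Merging peaks within 100 bp changed nothing because none were that close, and the motif comparison was not run. Of the other values, mostly lists and single genes, 693 stayed within their counting interval and 49 did not. No paired analysis was possible because each genotype has 1 library. The unknown depth limits all statements on weak peaks.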

Other observations

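Inside Podxl and Wt1, control cells had broad stretches of open chromatin that were not called in the cKO library. Control peaks covered 33.4 kb (75.1%) of Podxl, in 13 peaks, and cKO peaks 5.29 kb (11.9%), in 5. At Wt1 the control covered 35.7 kb (75.9%) in 14 peaks and the cKO 11.5 kb (24.4%) in 5. Over all 20 podocyte genes the cKO peaks covered 131 kb, 56.7% of the 232 kb of the control (percentile 0.1 of random lists, whose middle 95% was 63.6 to 86.1%). Coverage was lower in the cKO at 17 of them, a count not compared with random lists. Over all 21896 protein-coding genes the cKO peaks covered 83.0% as much as the control peaks. Without Podxl and Wt1 the share for the podocyte list was 70.4% (percentile 11.9), so its low coverage rested largely on those 2 genes. In a second list of 24 podocyte genes the share was 57.6% (percentile 0.02). Over the 20 podocyte genes, 57 of 112 distal control peaks inside the gene overlapped a cKO peak (50.9%, 41.3 to 60.5%), -17.1 points against the 68.0% expected for their strength. Distal peaks outside these genes were found in 61 of 99 cases (61.6%, with 70.6% expected) and peaks near a gene end in 34 of 41 (82.9%, with 86.9% expected). Among all assigned control peaks, distal peaks inside genes were found in 65.8% of 26538 cases and those outside in 71.5% of 20710, against 68.4% and 69.3% expected. These measures were chosen after the map of both genes had been seen, and coverage is not adjusted for peak strength.

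The second podocyte list, sharing no gene with the first, kept 159 of 261 control peaks (60.9%, 54.7 to 66.9%), -12.0 points against the 73.0% expected. At the actin cross-linker gene Actn4, 11 of 17 were found, at Dach1 8 of 18, at Arhgap24 9 of 15 and at Nebl 6 of 11, genes chosen after their values were seen. Inside these genes 90 of 166 distal peaks were found (54.2%, with 69.6% expected). Further nephron progenitor genes kept 99 of 119 (83.2%, percentile 97.92) and further interstitial genes 104 of 136 (76.5%, percentile 95.95). Further proximal tubule genes kept 39 of 53 (73.6%, 59.7 to 84.7%, percentile 86.21). This was 5.65 points above the 67.9% expected, so this list showed no loss in the main setting.

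The tests of a lower podocyte share, and of lower sensitivity behind the near-subset of cKO peaks, were chosen only after the result was seen, as was the setting with equal lengths and strength by p and area together; the others were set out before theirs were. The first pattern is the low recovery of podocyte peaks. It held in the second list (percentile 0.05) and without Podxl and Wt1 (percentile 1.02, -8.78 points over 193 peaks), which argues against 1 or 2 genes alone. Neither comparison was matched on gene length, so those 2 genes and gene length acting together were not excluded. Lower sensitivity of the cKO library would leave the list among the random lists if it acted on peaks of equal strength alike. The list stayed at percentile 0.04 with equal lengths and strength by p and area together. That premise was not tested. Over all assigned control peaks, distal peaks inside genes stood at -2.55 points against equal strength and those outside at 2.13. Loss was therefore not alike at equal strength, and lower sensitivity was not excluded. Matching on gene length left the list at percentile 0.57, although length-matched random lists already stood at -3.61 points. A lower share of podocytes among the sorted cKO cells may account for the pattern, as may less open podocyte genes per cell without Brg1, and these cannot be told apart: 100% of the list's 38 strongest peaks were found, which both allow.

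The second pattern is the high recovery of progenitor and interstitial peaks. If it were shared by such genes beyond the lists, both second lists should have lain in the highest 2.5% of random lists, and the lower of them, the interstitial one, was at 95.95. That list was in the highest 2.5% in 4 of 14 settings (percentiles 81.89 to 99.29, 2.32 to 8.63 points) and the second progenitor list in 6 (59.61 to 99.99, 0.37 to 16.1 points), but both together in 0 of the 14, where the lower percentile ran from 59.61 to 96.66. A higher recovery shared by both cell types was therefore not supported. It was not excluded either, since both second lists stood above peaks of equal strength in all 14 settings. Whether lists of their size can show differences this small was not simulated. A higher recovery in either type alone was not decided. Of the cKO peaks of the second lists, 96 of 102 progenitor and 104 of 109 interstitial peaks overlapped a control peak (percentiles 17.57 and 41.37). They were in the lowest 2.5% in 2 and 1 of the settings, with lowest percentiles of 0.96 and 0.49. No technical explanation was tested for this pattern.

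The third pattern is that cKO peaks were nearly a subset of control peaks. Lower sensitivity of the cKO library, from depth or background, and a partial loss across the genome without Brg1 would both remove weak peaks first, and cannot be told apart: 99.9% of control peaks in the strongest of 5 classes were found, a share too close to its limit to decide, and depth is unknown. Losses that follow strength class and position alone would be unrelated between neighbours after adjustment for both. The adjusted loss of adjacent control peaks within 50000 bp correlated at 0.0790 over 67973 pairs, across peaks within 1 comparison. In 100 permutations within these classes the correlation ran from -0.00835 to 0.0105. Strength still varies within a class, and the permutations do not account for neighbours alike in it. Peaks are not independent replicates and the correlation is small, so a regional part of the loss is a hypothesis only. A difference between genotypes was not testable with 1 library each.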
